A study of Homo sapiens with 18 samples.

How the data were processed

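The samples were 18 libraries of N-TERT keratinocytes, 3 for each combination of treatment (0 or 100 J/m2 UVB, 8 h incubation) and RNA source (whole cell lysate, monosomes or polysomes). Groups and replicate numbers were taken from the sample titles and treatment labels. Per the labels' protocols, RNA was isolated with Trizol, an RNA integrity number of at least 5 was required, and libraries were strand-specific, made from poly(A) mRNA and sequenced in pairs. Per the same protocols, ERCC spike-in Mix 1 was added to untreated and Mix 2 to treated samples. No spike-in values were found in the tables analysed here, so no library was scaled to them.

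Per the submitters' processing notes, reads were aligned with TopHat2 2.1.0 to hg19/GRCh37 and quantified with Cufflinks 2.2.1.0, and whole cell groups were compared with Cuffdiff, whose version is not given in the sources used here. The authors deposited FPKM values (fragments scaled to transcript length and to the mapped fragments of the library) for 82922 transcripts of each library, per the file headers, and replicates were not pooled. The deposited tables also hold the coverage of each transcript, its mean read depth per base as Cufflinks estimated it. For the fractions, the authors computed a percent in polysomes (polysome FPKM over the sum of polysome and monosome FPKM of the same replicate), its mean per treatment and the difference. Recomputing 175026 of these values from the FPKM gave a largest difference of 1.0e-13 percentage points. The authors' Cuffdiff table holds an FPKM per condition, a p-value and a q-value per transcript, per the file headers, and a short version of it gives the log2 fold change of 10 transcripts that the authors named. How Cuffdiff scaled the libraries, and whether strand was used in counting, is not given in the sources used here, so reads of overlapping loci may not be told apart.

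FPKM is relative to the rest of its library, so a change in many mRNAs shifts all others, and changes are also given against the median of all loci. The number of reads per library is unknown. Coverage divided by FPKM, which scales with it, was 1.87 to 2.97. Cufflinks reported a failed estimate for 88 transcripts in at least 1 library, and the 18 loci holding one were left out. Replicates of one group correlated at 0.970 to 0.994 on the log scale, and no pair of libraries was identical.

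Transcripts were summed to 30712 loci by the locus identifiers of the authors' Cuffdiff table, which covered 82828 transcripts. Coordinates are those of the tables, on hg19 and counted from 1, of the transcript where its identifier is given and otherwise of the locus. The span of a locus is its genomic length from first to last base, and its spliced length is that of its transcript with the highest mean FPKM in whole cell RNA. The tables pair symbols with 10 transcripts alone. The reference tables used for names matched 1 identifier, through a synonym, and it was not used. The reference genome at hand was of another build, so no names were taken from coordinates.

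Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on log2(FPKM + 1), for loci with a mean of at least 1 FPKM over the libraries tested, with Benjamini-Hochberg adjustment over all loci of a comparison and a threshold of 0.05. Fold changes are on this log2 scale, which understates the change of low values. The 6 whole cell libraries were fitted by themselves. The 12 fraction libraries were fitted together with 1 mean per group and 1 shared spread, and the change of the polysome to monosome ratio was the interaction of treatment and fraction. Named transcripts were tested singly in the same way, adjusted over all transcripts, and their change is not that of their locus where it holds several. On simulated data with 100 changed loci per size, the whole cell test found 29% of log2 changes of 0.5 and 80% of 1 (11678 loci), the polysome test 41% and 87%, and the ratio test 15% and 63% (10506 loci each). Far more loci were called in the data (8853 in whole cell RNA), and the adjustment is less strict when more loci change. These shares therefore do not give the sensitivity of the tests reported here. The median percent in polysomes of the replicates was compared by an exact two-sided permutation test.

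The tests, the alternatives and the rule for naming genes were fixed before the data were examined, except where the text says otherwise. That rule asked for the 10 largest rises and falls with a gene symbol, members of fixed gene lists, and p21 and p53 in every case. Since almost no identifier has a symbol here, the gene lists, the markers of other cell types and most of the rule were not analysed, and genes are named only where the authors named them. The transcript that the authors named DDB1 (uc001nra.3) stayed under 1 FPKM and was not tested. That name could not be checked here and is in doubt, so its values give no level of DDB1 mRNA. By the same rule of size, 2 loci that rose and 2 that fell are given by identifier, after requiring a mean of at least 5 FPKM, all UVB libraries on one side of the untreated ones and, as an added condition, values above 0 in all 6 libraries.

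Alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, rescaling by the median ratio to the geometric mean library, quantile normalization, the replicate number as a block, a mean-variance trend with robust fitting, and leaving out each replicate. Added after seeing the data were the counts over other splits of the libraries, loci above 0 in all libraries, tests of single transcripts, and groups of loci by spliced length, lack of introns and the mitochondrial genome.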

Results

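Messenger RNA was sequenced from N-TERT keratinocytes, an immortalised line of human skin keratinocytes, that were left untreated (0 J/m2) or exposed to 100 J/m2 of broadband UVB and then kept for 8 h. RNA came from the whole cell lysate, from the monosome fraction (mRNA carrying a single ribosome) and from the polysome fraction (mRNA carrying several), with 3 libraries for each of the 6 groups. The design asks how UVB changes the amount of each mRNA and how it is divided between the fractions. Values were Cufflinks FPKM, summed over the transcripts of a locus for the counts of changed loci. The number of reads behind them is unknown, but the mean depth per base that stood behind 1 FPKM was 1.87 to 2.97 over the 18 libraries. It was lower in the UVB whole cell libraries (1.87, 2.40 and 2.49) than in the untreated ones (2.85, 2.85 and 2.75), so low values were less precise after UVB. The labels do not say that the replicates were separate cultures, so each p-value measures only the spread between these samples, which may be technical.

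In whole cell RNA, the mRNA of the CDK inhibitor p21, a textbook target of p53, rose after UVB while that of cyclin D1, which drives entry into S phase, fell. The p21 locus (hg19 chromosome 6, 36644237 to 36655116, 5 transcripts) went from 311 ± 19.996 to 756 ± 13.1 FPKM (SD, n = 3), a log2 change of 1.28 (SE 0.070, adjusted p = 2.87e-05), or 1.65 above the median of all loci. This sum counts the V4 transcript, listed at 0 before UVB, and with quantile normalization its change was 0.73. Cyclin D1 (uc001opa.3, chromosome 11, 69455873 to 69469242) went from 79.8 ± 4.24 to 23.3 ± 1.46 FPKM, a log2 change of -1.73 (SE 0.088, adjusted p = 1.12e-04). Of the NF-kappaB pathway, IKBa, the inhibitor that holds NF-kappaB in the cytoplasm, (uc001wtf.4, chromosome 14, 35870716 to 35873960) rose from 51.6 ± 9.65 to 98.6 ± 8.49 FPKM (log2 change 0.94, SE 0.16, adjusted p = 0.0055). The nfkb1 transcript (uc011cep.2, chromosome 4, 103422486 to 103538459) fell from 19.9 ± 0.153 to 4.43 ± 1.73 FPKM (log2 change -2.00, SE 0.26, adjusted p = 0.0019), and the RELA transcript (uc001ofg.3, chromosome 11, 65421067 to 65430443) stood at 41.7 ± 2.51 and 38.5 ± 2.02 FPKM (adjusted p = 0.32). The loci of cyclin D1 and IKBa hold 1 transcript each. The nfkb1 locus holds 3 and its sum changed by -1.52 (adjusted p = 2.27e-05), and the RELA locus holds 8 and its sum did not pass (-0.11, adjusted p = 0.22). That RELA value is also the change of its transcript, so the sum is not a separate result.

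A pair of p21 transcripts carried names in the authors' table, and they differed in the untreated cells. Variant V1 (uc003omm.4) rose from 311 ± 19.996 to 588 ± 20.9 FPKM in whole cell RNA (log2 change 0.92, SE 0.084, adjusted p = 6.47e-04; 0.36 with quantile normalization, adjusted p = 0.016). Variant V4 (uc003omn.3) was listed at 0 in all 9 untreated libraries. After UVB, V4 stood at 168 ± 13.7 FPKM in whole cell RNA, 175 ± 52.7 in monosomes and 325 ± 17.3 in polysomes (SD, n = 3). V4 then made up 22.2% ± 1.92 of the FPKM of its locus in whole cell RNA, 25.7% ± 1.27 in monosomes and 20.3% ± 0.837 in polysomes (SD, n = 3). A fold against values listed at 0 was not computed, because such a value can be a failed estimate. The authors' deposited table of both conditions gives V4 as 10.1 FPKM untreated and 192 FPKM after UVB (q = 2.67e-04), so V4 was above 0 there.

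**Figure D1:**
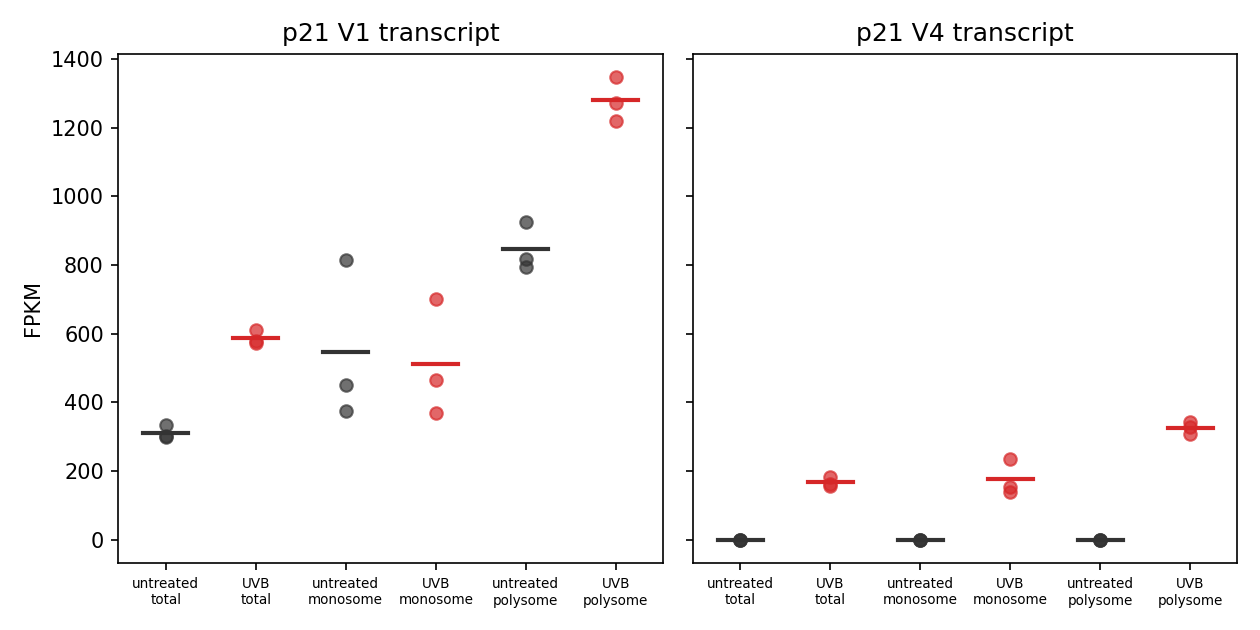
FPKM of the p21 transcripts V1 (left) and V4 (right) in each library, untreated in black and UVB in red, with a bar at the mean of each group of 3 libraries. V4 is listed at 0 in all untreated libraries and lies between 137 and 342 FPKM in the UVB libraries, and V1 is above 0 in all groups.

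Among the other transcripts that the authors named, those of p53BP and ATM fell and that of the tumour suppressor p53 did not pass the test. The p53BP transcript (uc001zrr.4, chromosome 15, 43699412 to 43785354) went from 9.90 ± 0.384 to 2.38 ± 1.45 FPKM (log2 change -1.80, SE 0.38, adjusted p = 0.0104), with a UVB replicate 1 of 0.715 against 3.00 and 3.41 in the others. With a pseudocount of 5 its change was -1.03. The transcript of ATM, the kinase that responds to DNA double-strand breaks (uc001pkb.1, chromosome 11, 108093559 to 108239826), went from 1.88 ± 0.507 to 0.331 ± 0.143 FPKM (log2 change -1.11, SE 0.16, adjusted p = 0.0028). At this low level the size of the ATM change rested on the pseudocount (-2.22 with 0.1, -0.37 with 5), and quantile normalization ended the call (-0.38, adjusted p = 0.13). The p53 transcript (uc002gij.3, chromosome 17, 7571720 to 7590868) stood at 39.6 ± 3.52 FPKM untreated and 39.5 ± 1.75 FPKM after UVB (adjusted p = 1.00), which lay 0.36 above the median change of all transcripts. The sums over their loci changed by -1.46 for p53BP (6 transcripts, adjusted p = 5.43e-05) and -1.01 for ATM (9 transcripts, adjusted p = 0.0038). With quantile normalization these were -0.75 for p53BP (adjusted p = 1.22e-04) and -0.37 for ATM (adjusted p = 0.039). The sum over the p53 locus (17 transcripts) did not pass (adjusted p = 1.00) except with median-ratio rescaling (0.40, adjusted p = 0.018). Before rescaling, the change of this sum was that of the p53 transcript itself. The authors' deposited table gives p53 a log2 change of 0.47 (q = 0.0227) and RELA one of 0.36 (q = 0.0263). For each of the 6 named transcripts that passed in whole cell RNA (p21 V1, IKBa, cyclin D1, nfkb1, p53BP and ATM), all 3 UVB libraries lay on one side of all 3 untreated ones. The authors chose these names in a table made from these samples, so their changes are not independent evidence of a direction.

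Across all loci, the longer a gene was on the chromosome, the more often it fell in whole cell RNA. Of 2975 loci that span under 10 kb, 50.99% rose and 19.7% fell, with a median log2 change of 0.34. Of 5028 loci of 10 to 50 kb, 21.1% rose and 50.5% fell (median -0.33). Of 2654 loci of 50 to 150 kb, 6.67% rose and 78.5% fell (median -1.03), and of 1021 loci over 150 kb, 4.51% rose and 82.4% fell (median -1.08). Set against the median of all loci, these medians were 0.71, 0.04, -0.66 and -0.71. After rescaling by median ratios they were 0.70, 0.03, -0.70 and -0.77, and with quantile normalization 0.49, 0.04, -0.49 and -0.50, so the class of 10 to 50 kb changed sign and the others did not. Spearman's rho between span and change was -0.556 across 11678 loci, which are not independent replicates.

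**Figure D2:**
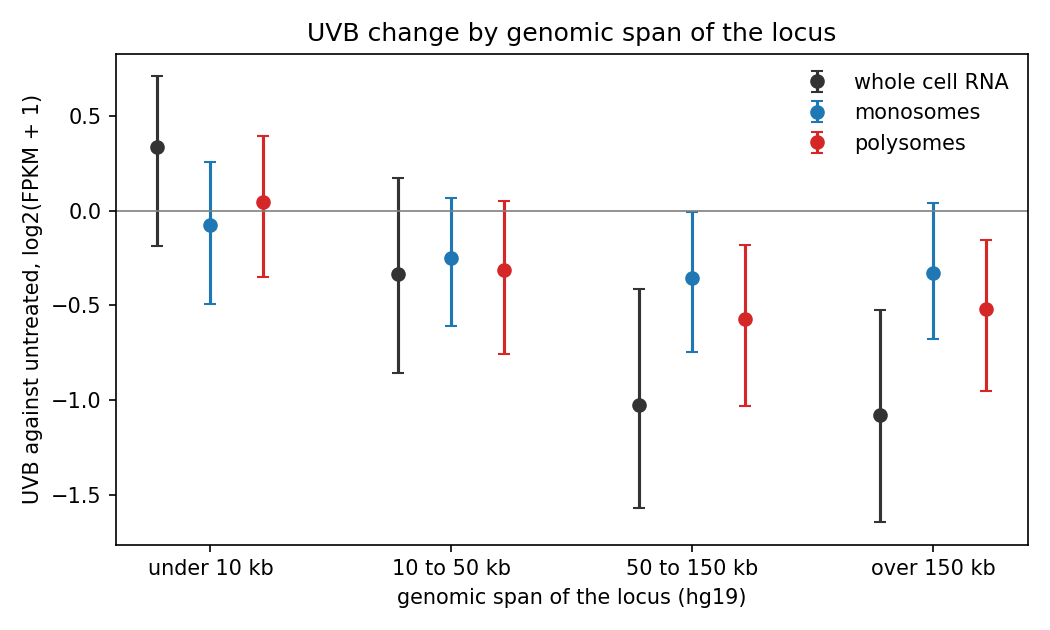
UVB change in log2(FPKM + 1) by genomic span of the locus, in whole cell RNA, monosomes and polysomes; points are medians over loci and bars run from the lower to the upper quartile. The whole cell median goes from 0.34 under 10 kb to -1.08 over 150 kb, and the polysome and monosome medians over 150 kb are -0.52 and -0.33. With median-ratio rescaling, the medians over 150 kb become -0.77 in whole cell RNA, -0.15 in polysomes and -0.02 in monosomes. Under that rescaling the median of all tested loci is -0.01 in whole cell RNA, 0.13 in polysomes and 0.08 in monosomes.

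In total, limma called 8853 of 11678 tested loci changed in whole cell RNA, 2802 higher and 6051 lower after UVB. Among loci without a name and above 0 in all 6 libraries, a condition that left out 13 loci with a larger fall and 2 with a larger rise, the largest rise was at XLOC_009956. This locus (chromosome 15, 75011883 to 75017877) stood at 0.801, 0.847 and 0.792 FPKM untreated and at 111, 124 and 125 FPKM after UVB (log2 change 6.06, adjusted p = 4.09e-07). XLOC_001235 (chromosome 1, 212738676 to 212794119) changed by 5.55 (adjusted p = 1.57e-06). The largest falls under that condition were -3.54 at XLOC_019056 (chromosome 3, 30647994 to 30735633, adjusted p = 1.32e-05) and -3.13 at XLOC_004739 (chromosome 11, 128556430 to 128683162, adjusted p = 3.10e-06; -1.71 with a pseudocount of 5). The balance of higher and lower calls depended on the scaling of the libraries: the median change of all loci was -0.37 as deposited, and rescaling by median ratios gave 4338 higher and 4413 lower, quantile normalization 4147 and 3978. The authors' deposited table calls 7859 of 24965 tested transcripts changed at q under 0.05, 4183 higher and 3676 lower. With limma on single transcripts, 9612 of 16624 passed, 3000 higher and 6612 lower. The sets of transcripts tested differ.

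In polysomes, cyclin D1 fell from 29.1 ± 2.82 to 12.4 ± 0.200 FPKM (SD, n = 3; log2 change -1.16, SE 0.17, adjusted p = 6.45e-04; -0.75 with median-ratio rescaling). The p21 V1 transcript went from 846 ± 70.7 to 1280 ± 64.4 FPKM, which did not pass (log2 change 0.60, SE 0.29, adjusted p = 0.15) except with median-ratio rescaling (1.02, adjusted p = 0.024) and without replicate 3 (0.59, adjusted p = 0.048). All its UVB polysome values (1273, 1348 and 1219 FPKM) lay above the untreated ones (927, 818 and 794). Its SE is shared with the monosomes, where untreated V1 stood at 450, 374 and 816 FPKM, so the missed call does not measure the polysome spread alone. The sum over the p21 locus, in which V4 counts as 0 before UVB, reached 1605 ± 74.2 FPKM and passed (log2 change 0.93, SE 0.27, adjusted p = 0.0129). Its change was 1.44 with median-ratio rescaling, and its call was lost without replicate 1 (0.99, adjusted p = 0.063) or replicate 2 (0.87, adjusted p = 0.090). The named transcript of RELA, a subunit of NF-kappaB, fell from 63.6 ± 1.17 to 47.8 ± 2.82 FPKM (log2 change -0.41, SE 0.13, adjusted p = 0.037). That call was lost under quantile normalization (-0.31, adjusted p = 0.10) and without replicate 1, 2 or 3 (adjusted p = 0.19, 0.0998 and 0.13), and its direction turned with median-ratio rescaling (0.010, adjusted p = 1). The sum over the RELA locus changed by -0.41 (adjusted p = 0.0015), by -0.25 with quantile normalization (adjusted p = 0.030) and by 0.09 with median-ratio rescaling (adjusted p = 0.56). Before rescaling, the change of that sum is the value of the transcript itself with a smaller SE (0.084), so it is not separate evidence. IKBa went from 65.3 ± 10.6 to 95.7 ± 9.61 FPKM and missed the threshold when tested among transcripts (log2 change 0.55, adjusted p = 0.073). It passed with median-ratio rescaling (0.97, adjusted p = 0.0077), a replicate block (adjusted p = 0.018), a pseudocount of 5 (adjusted p = 0.0498) and without replicate 3 (adjusted p = 0.0115). Tested among loci, where its locus holds this transcript alone, the same values passed (adjusted p = 0.035). They also passed there with median-ratio rescaling (adjusted p = 0.0015) and quantile normalization (adjusted p = 0.023). The sum over the p53 locus changed by -0.44 (adjusted p = 0.0081), by -0.36 with quantile normalization (adjusted p = 0.032) and by 0.06 with median-ratio rescaling (adjusted p = 0.74). The sum over the nfkb1 locus changed by -1.10 (adjusted p = 8.60e-06) and that over the p53BP locus by -0.95 (adjusted p = 9.33e-05). With median-ratio rescaling these were -0.65 and -0.58, and both passed. Over all loci, 6241 of 10506 changed, 1491 higher and 4750 lower, with a median of -0.28. Median-ratio rescaling gave 3684 higher and 2498 lower, quantile normalization 2551 and 2798. With median-ratio rescaling the median of the tested loci was 0.13, so its higher calls of loci include that offset.

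Most loci that fell in whole cell RNA also fell in polysomes. Of 10131 loci tested in both, 3865 fell in both and 904 fell in whole cell RNA without passing in polysomes. A rise in both was called at 1258 loci and a rise in whole cell RNA alone at 1428, while 70 rose in whole cell RNA and fell in polysomes and 25 did the opposite. These counts depended on the scaling. Median-ratio rescaling gave 2127 loci that fell in both and 1120 that fell in whole cell RNA without passing in polysomes, and quantile normalization 1957 and 1118. For the rises, the former gave 3171 and 1080 and the latter 2116 and 1749. Spearman's rho of the changes was 0.834 across loci, between separate sets of libraries. By span, the polysome medians were 0.04, -0.32, -0.57 and -0.52 from the shortest to the longest class, or 0.32, -0.04, -0.30 and -0.24 against the median of all loci. With median-ratio rescaling they were 0.49, 0.11, -0.19 and -0.15, where the median of all tested loci was 0.13. With quantile normalization, where that median was 0.005, they were 0.19, -0.01, -0.19 and -0.12. The class of 10 to 50 kb lay above 0 with the former, but below the median of all loci. The smaller falls of the longer classes with the former include that offset, so they do not show a weaker relation to span. With quantile normalization these falls were smaller against the median of all loci too.

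In monosomes, the p53 transcript rose from 10.4 ± 1.05 to 15.0 ± 0.624 FPKM (log2 change 0.49, SE 0.097, adjusted p = 0.0038, SD over n = 3) and cyclin D1 fell from 15.0 ± 3.86 to 5.69 ± 0.995 FPKM (log2 change -1.24, SE 0.17, adjusted p = 4.97e-04). The p53 change was 0.79 with either rescaling, and its call was lost without replicate 1 (adjusted p = 0.065) or replicate 2 (adjusted p = 0.065). This rise was of 1 transcript: the sum over the 17 of the p53 locus changed by -0.24 (adjusted p = 0.12). The sum over the p21 locus stood at 547 ± 236 FPKM untreated and 687 ± 224 after UVB (log2 change 0.36, adjusted p = 0.28), and it passed with median-ratio rescaling (0.77, adjusted p = 0.045) and without replicate 3 (0.45, adjusted p = 0.035). Over all loci, 5727 of 10506 changed, 1440 higher and 4287 lower, with a median of -0.23. Median-ratio rescaling gave 3157 higher and 2247 lower, quantile normalization 2703 and 2833. With median-ratio rescaling the median of the tested loci was 0.08, so its higher calls of loci include that offset. The spread of all these monosome tests is shared with the polysomes. Replicates correlated at 0.981 to 0.988 in monosomes and at 0.991 to 0.994 in polysomes, so the shared spread may be too small for monosome calls. The changes in monosomes had a rho of 0.750 with those in polysomes and 0.604 with those in whole cell RNA.

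Between the fractions, the balance of the p53 transcript shifted towards monosomes after UVB. Its polysome to monosome ratio fell by 0.76 on the log2 scale (SE 0.14, adjusted p = 0.01003), which lay 0.69 below the median of all transcripts. Its percent in polysomes, the polysome FPKM over the sum of both fractions, was 83.2% ± 1.06 untreated and 74.0% ± 1.51 after UVB (SD, n = 3), lower in all 3 UVB replicates. The p53 call was lost without replicate 1 (-0.74, adjusted p = 0.19), without replicate 2 (-0.73, adjusted p = 0.14) and with median-ratio rescaling (-0.64, adjusted p = 0.075). The ratio of the sum over the p53 locus did not pass (-0.21, adjusted p = 0.44). Of the other named loci, the ratio of the sum fell at p53BP (-1.42, adjusted p = 0.0012) and nfkb1 (-0.88, adjusted p = 0.0056). Both passed with median-ratio rescaling (-1.36 and -0.75) and quantile normalization (-1.31 and -0.72). Fits with a replicate left out are not given for these sums. The named nfkb1 transcript showed no clear direction: it stood at 56.9% ± 51.4 untreated and 71.4% ± 31.0 after UVB in polysomes. Its ratio changed by -0.37 (adjusted p = 0.90). The p53BP sum changed by -0.95 in polysomes and by 0.47 in monosomes (adjusted p = 9.33e-05 and 0.0101). Its named transcript was listed at 0 in all untreated monosome libraries, which may be a failed estimate. For p21 the ratio did not pass (locus log2 change 0.56, SE 0.39, adjusted p = 0.35), and the V1 transcript stood at 61.7% ± 10.8 and 71.8% ± 7.39 in polysomes. Cyclin D1 stood at 66.4% ± 3.61 and 68.8% ± 3.56 (adjusted p of the ratio = 0.88), and IKBa at 65.9% ± 4.44 and 74.6% ± 0.203 (adjusted p = 0.27).

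Over all loci, the ratio changed at 1551 of 10506, 520 higher and 1031 lower. This count rested on few libraries: 47 higher and 75 lower passed without replicate 1, 107 in all without replicate 2 and 1124 without replicate 3, and 857 passed with median-ratio rescaling (375 higher, 482 lower). Quantile normalization gave 651 higher and 776 lower. The median percent in polysomes over loci was 58.9 ± 0.774 untreated and 57.4 ± 0.932 after UVB (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The median shift over 10277 loci was -0.82 percentage points, with quartiles of -5.85 and 3.61, and it was 0.037 when only loci of at least 5 FPKM were used. The authors' deposited table of percent shifts has a median of -1.44 percentage points over 19293 transcripts. FPKM are scaled within the library of each fraction, so these percents are relative and are not shares of mRNA molecules. A move of all mRNAs from one fraction to the other would not appear in them or in their test.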

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

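The count over splits of the fraction libraries, and its breakdown, were chosen only after the data were seen. Tests of the difference itself, over all loci and for named transcripts, picked out 2 results whose UVB change differed between polysomes and monosomes. The sums over the p53BP and nfkb1 loci also differed (-1.42 and -0.88, adjusted p = 0.0012 and 0.0056), as given above. The first of the 2 results is the 1551 loci whose ratio of the fractions changed. Drawn splits of the 12 fraction libraries gave as many loci in 7 of 100, the real one included, with a highest other count of 4351. This count can neither exclude chance nor speak for it, because the UVB change enters the other splits. All 6 of the others with as many were among the 8 that kept all 3 untreated polysome libraries together, and the highest of the rest gave 285. All other drawn splits mix untreated and UVB libraries in at least 1 fraction, so the UVB change enters their spread or their difference and they give no count free of it. Those 6 splits divided the polysome libraries by treatment and mixed treatments in monosomes, so the UVB change in polysomes is part of their difference. Why counts varied among the 8 splits was not tested. The count fell to 107 without replicate 2 and to 47 higher and 75 lower without replicate 1, so its size stays open.

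The p53 transcript is the other one, with a UVB change in polysomes that was lower than in monosomes by a log2 difference of -0.76 (-0.27 against 0.49). Its percent in polysomes was 82.3, 84.4 and 82.9 untreated and 72.2, 74.7 and 74.97 after UVB. The adjusted p was 0.01003, and over the alternatives it ranged from 0.0033 with no filter on low values to 0.19 without replicate 1. The sum over the 17 transcripts of the p53 locus had a difference of -0.21 (adjusted p = 0.44), so the call was made for a single transcript and not for the sum. That sum changed by -0.44 in polysomes (adjusted p = 0.0081) and by -0.24 in monosomes (adjusted p = 0.12).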

How the results depend on the processing

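Counts of changed loci stayed within 1.5 times under all alternatives but these. With a mean of at least 5 FPKM, where fewer loci are tested, 3735 loci passed in polysomes and 3650 in monosomes. The ratio of the fractions gave 857 with median-ratio rescaling, and 107 (without replicate 2) to 1124 with 1 replicate left out, where fewer samples enter. The cause of the change with rescaling was not tested. The replicate block gave 7797 loci in whole cell RNA, 6235 in polysomes, 5773 in monosomes and 1442 for the ratio. Same-numbered libraries of 2 groups correlated at -0.24 to 0.20 in their deviations, so the main tests did not pair samples by number. The percents in polysomes do pair the fractions of the same number, as the authors did. The block gives each number 1 effect across all groups of a fit, so it does not model a pairing of fractions within a treatment. The rho of span and change was -0.550 at 5 FPKM or more, -0.572 over loci above 0 in all libraries (added after seeing the data), and -0.563 to -0.548 with 1 library left out. The median shift in percent in polysomes was 0.037 at 5 FPKM or more, and -0.42 to -1.17 otherwise.

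Of 407 alternative values for the named transcripts, the p21 locus and the loci given by identifier, 357 kept direction and side of the threshold, 12 lost and 12 gained the threshold, and 26, all of named transcripts, changed sign. Of the 26, 1 had passed as reported, RELA in polysomes, 0.010 with median-ratio rescaling. With that rescaling, RELA (0.24) and p53 (0.35) also turned in whole cell RNA, p53 (0.15) and nfkb1 (0.081) in polysomes, and IKBa (0.27) and p21 V1 (0.25) in monosomes. Quantile normalization turned p53 in whole cell RNA (0.033), nfkb1 in polysomes (0.19), and IKBa (0.13) and p21 V1 (0.025) in monosomes. A pseudocount of 0.1 turned nfkb1 in polysomes (0.65) and in the ratio (0.16), and one of 5 turned cyclin D1 in the ratio (-0.075). With 1 library left out, p53 in whole cell RNA ranged from -0.047 to 0.069. With 1 replicate left out, nfkb1 ranged from -0.57 to 1.49 in monosomes, -1.08 to 0.52 in polysomes and -0.97 to 0.38 in the ratio, p21 V1 from -0.25 to 0.048, RELA from -0.074 to 0.20 and IKBa from -0.13 to 0.14 in monosomes. The cause was not tested.

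Not run were the gene lists with their alternatives (no symbols for almost all identifiers) and scaling to spike-ins (no such values in the tables used). The number of reads is unknown, which limits what can be said of low values.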

Other observations

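The groups by spliced length, lack of introns and the mitochondrial genome, the comparison by intron length, and the splits of the libraries, were chosen only after the data were seen. Of 8 loci of the mitochondrial genome in polysomes, 3 rose and none fell, with a median log2 change of 0.69. That median was 1.02 with median-ratio rescaling and 0.78 with quantile normalization. In whole cell RNA, 6 such loci had a median of 0.45 (3 rose and none fell), which turned to -0.05 with quantile normalization. Mitochondrial loci held 3.67 to 5.44% of the FPKM in monosome libraries and 0.16 to 0.36% in polysome libraries. Loci without introns had a median of 0.12 in whole cell RNA over 590 loci, or 0.49 against all loci, with 175 that rose and 155 that fell. By spliced length, the whole cell medians were 0.49 under 1 kb, 0.10 at 1 to 2 kb, -0.44 at 2 to 4 kb and -1.04 over 4 kb, or 0.87, 0.47, -0.07 and -0.67 against all loci. The median change of the polysome to monosome ratio was 0.15, -0.08, -0.24 and -0.25 from the shortest to the longest span class, with a rho of -0.360 between span and change. With median-ratio rescaling these medians were 0.24, 0.03, -0.13 and -0.15, and with quantile normalization 0.14, -0.01, -0.10 and -0.12.

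Loci with a longer genomic span fell more in whole cell RNA (rho -0.556). Spliced length as the whole cause is argued against by the rho of span given spliced length, -0.378, estimates listed at 0 by the rho of -0.572 over loci above 0 in all 6 libraries, and values near the pseudocount by the rho of -0.512 over loci of at least 20 FPKM. Whether UVB damage stopped transcription along the gene stays open: intron length given spliced length had a rho of -0.379, but intron length had a rho of 0.997 with span, so this value repeats that of span. Other effects stay open too: spliced length given span kept a rho of -0.360, and RNA breakage before poly(A) selection, which could lower long transcripts, and differences in mRNA stability were not tested. The 10 splits of the 6 libraries are too few to give a share under 0.05, and the highest other split had a rho of 0.540 in size against the real -0.556. Each other split holds 2 libraries of one treatment against 1 in each group, so it carries part of the UVB change and its rho is not one of chance.

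A total of 58 loci were listed at 0 in all untreated whole cell libraries and 72 in all UVB ones while the other group had a mean of at least 5 FPKM. They overlapped another locus in 70% of cases, against 33.7% of all tested loci, a ratio of 2.08, so a candidate explanation is that reads were given to an overlapping locus. In the authors' deposited table, 39.2% of them stood at 1 FPKM or more in the group listed at 0, which lies between the values set beforehand for and against an effect of the estimation per library, so that explanation stays open. The p21 variant V4 shares its locus with V1 and 3 other transcripts, and its 0 in the untreated libraries has the same limit.

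For the counts of changed loci, each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. The real split gave 8853 loci in whole cell RNA, 6241 in polysomes and 5727 in monosomes, against highest other counts of 3, 2 and 7, and 1 split of 10 reached each real count. All the other splits mix treatments within both groups, which adds the UVB change to the spread and lowers their counts, so these give no level of chance.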
